A study of Arabidopsis thaliana with 2 samples.

How the data were processed

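The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from Arabidopsis thaliana seedlings of the Col-0 background. ChIP-seq recovers and sequences the DNA that a chosen protein is cross-linked to. The plants were cca1 lhy double mutants carrying CCA1 fused to a FLAG epitope tag under the CCA1 promoter, so an anti-FLAG antibody pulls down the tagged protein. Per the labels' protocols, whole seedlings aged 14 days were grown at 22 °C on medium with 2% sucrose in cycles of 12 h light and 12 h dark and were fixed 1 h after lights on. One library was read on an Ion PGM (called IonPGM here) and 1 on an Illumina GAII (called Illumina here). The labels do not say whether both came from the same immunoprecipitated DNA or from separate plants. With 1 library per sequencer there is no biological replicate check, and library preparation kit and sequencer cannot be told apart.

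Per the submitters' processing notes, the tools were Bowtie 0.12.7, SAMtools 0.1.18 and MACS2 (version not given there), with the TAIR10 build. The peak threshold, any control library and any filter are not given in the sources used here. The deposited values are 1 peak list per sequencer with the position of each peak and 1 score per peak, which is the authors' own value from the peak caller. The scale of that score is not given, so it served only to rank peaks within a list, as a percentile from 0 to 100. Read counts and depth are unknown, so no interval or detection limit could be set on the signal of a peak. Both files were read as 0-based half-open intervals, and positions are printed 1-based.

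Peaks were called per sample. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and the stretch common to both is called a shared segment. The observed sharing was set against 1000 random placements of each list on its own chromosomes, with the last annotated gene or peak taken as the chromosome's end. The median score percentile of shared and unshared peaks was compared with a two-sided permutation test (100000 resamples).

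Gene names came from a table of NCBI RefSeq genes on TAIR10.1, the release whose nuclear chromosome sequences are those of TAIR10. As a check of the match, shared segments were moved along the chromosomes. At their own position 44.0% of their centres lay within 500 bp outside a gene end, against 22.5% after a move of -2000 bp and 20.2% after a move of 2000 bp. No gene coordinate from that table is printed, and the chloroplast and mitochondrial genomes, whose sequences differ between the releases, were left out of every gene assignment. The table gives neither strand nor exons, so the start of a gene could not be told from its end and exon, intron and UTR positions were not assigned. The planned window of 1000 bp upstream to 200 bp downstream of the transcription start was therefore replaced by 1000 bp outside to 200 bp inside either gene end. A gene is called bound when a shared segment overlaps that window by at least 1 bp. A centre more than 200 bp from both ends of a gene that contains it is called inside the gene.

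The tests were applied to 27444 nuclear protein-coding genes. The 11 gene lists were fixed before the data were examined, hold 167 genes, and all 167 were found by locus identifier. For 160 of these the table also gives the symbol used here as symbol or synonym. Each list was compared with all other genes by a one-sided Fisher's exact test for excess, with Benjamini-Hochberg adjustment over the 11 lists. These p-values treat genes, and the others treat peaks, as the units: they describe these 2 lists and not the spread between plants. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only. Gene-poor regions are the 121 of 1193 bins of 100 kb that hold at most 6 protein-coding genes.

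The rule for naming genes was also fixed beforehand. It takes every member of the evening and morning clock lists, up to 4 bound members of each other list by mean score percentile, the genes at the 10 highest-ranked shared pairs, and the nearest genes of the 3 highest unshared peaks of each list. The planned tests of sequence motifs, the evening element among them, were not run because no genome sequence was used here. Alternatives tried were other overlap rules, score thresholds, gene windows, peak sets and backgrounds.

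The code was tested on simulated data. For the overlap of 2848 nuclear IonPGM peaks, planted sharing of 50.7% was recovered as 50.9%, and 0 planted sharing as 1.47%. For the gene lists, tested over 27444 genes, all 100 planted lists and 2 of 450 unplanted lists were called. These lists held random genes, most members of a planted list were given a peak, and the other peaks were placed at random. Real peaks gather at gene ends and some real lists hold few bound genes, so these rates need not hold for the real lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.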

Results

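Binding of CCA1 was mapped in seedlings fixed 1 h after lights on. CCA1 is a MYB-type transcription factor of the circadian clock whose expression peaks around dawn. The IonPGM list held 2901 peaks, of which 2848 were on the nuclear chromosomes, 50 on the chloroplast and 3 on the mitochondrial genome. The Illumina list held 2954 peaks, of which 2888 were nuclear, 49 chloroplast and 17 mitochondrial. Median peak width was 253 bp in the IonPGM list and 275 bp in the Illumina list, and the peaks covered 892 kb and 904 kb in total. Each group holds 1 library of unknown depth, so no value below has a replicate error.

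The first comparison asks how far the 2 sequencers placed CCA1 at the same sites. Part of each list was found again by the other sequencer, and the strongest common site lay at CCA1 itself. The shares of both lists are close by construction, because the lists are of similar length and most shared peaks overlapped a single peak. Of the IonPGM peaks, 1514 (52.2%, 95% interval 50.4 to 54.0%) overlapped an Illumina peak, and of the Illumina peaks 1523 (51.6%, 49.7 to 53.4%) overlapped an IonPGM peak. Random placement gave 1.95% and 1.92% on average and at most 2.86% and 2.81%, so the placement p was 0.001 on both sides, the smallest that 1000 placements can give.

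The 10 highest-ranked shared pairs named a compact set of genes. The first, with the highest score of both lists, lay across one end of CCA1 (AT2G46830) at chromosome 2: 19245162 to 19245676 in the IonPGM list and 19245186 to 19245693 in the Illumina list, and PSI-P also has an end within 1000 bp of it. The second lay outside GI (AT1G22770), a clock and flowering gene expressed late in the day, at chromosome 1: 8060665 to 8061226 (IonPGM). The third lay across one end of ELF4 (AT2G40080), a member of the evening complex of clock repressors, at chromosome 2: 16734846 to 16735282 (IonPGM). Ranks 5 to 10 included peaks at BBX8 and AT5G48270, at GRP7 (a glycine-rich RNA-binding protein under clock control) and AT2G21680, at FKF1 (a blue-light photoreceptor F-box protein), at PORB (protochlorophyllide oxidoreductase, of chlorophyll synthesis) and AT4G27435, and at BBX13 and AT1G28060. Ranks 4 and 7 had no protein-coding gene in the window and lay in gene-poor regions, nearest to AT4G06688 on chromosome 4 and to AT3G32980 on chromosome 3.

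Peaks with higher scores were shared more often. The median score percentile was 63.4 for shared and 35.7 for unshared IonPGM peaks, and 65.4 and 36.1 for Illumina peaks (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). In the Illumina list the shared part went from 30.3% in the lowest decile to 88.5% in the highest. In the IonPGM list it went from 25.8% in the lowest decile to 78.2% in the ninth and was 72.5% in the highest, or 83.5% in the highest once gene-poor regions were left out. Across the 1532 overlapping pairs the scores of the 2 lists had a Spearman rho of 0.47 (permutation p = 1e-05, the smallest possible). That correlation is across peaks, which are not independent replicates.

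**Figure D1:**
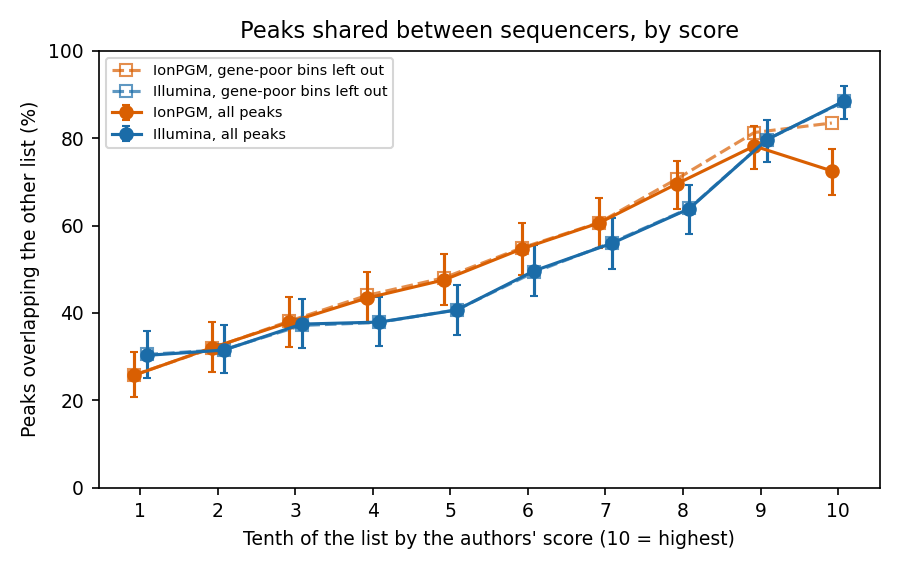
Percentage of peaks that overlap a peak of the other list (y axis) in each decile of a list by the authors' score (x axis, 10 is the highest), for IonPGM (orange) and Illumina (blue). Filled points are all peaks with exact 95% intervals and open squares leave out gene-poor regions: sharing is 88.5% in the highest Illumina decile and 72.5% in the highest IonPGM decile, 83.5% without gene-poor regions.

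**Figure D2:**
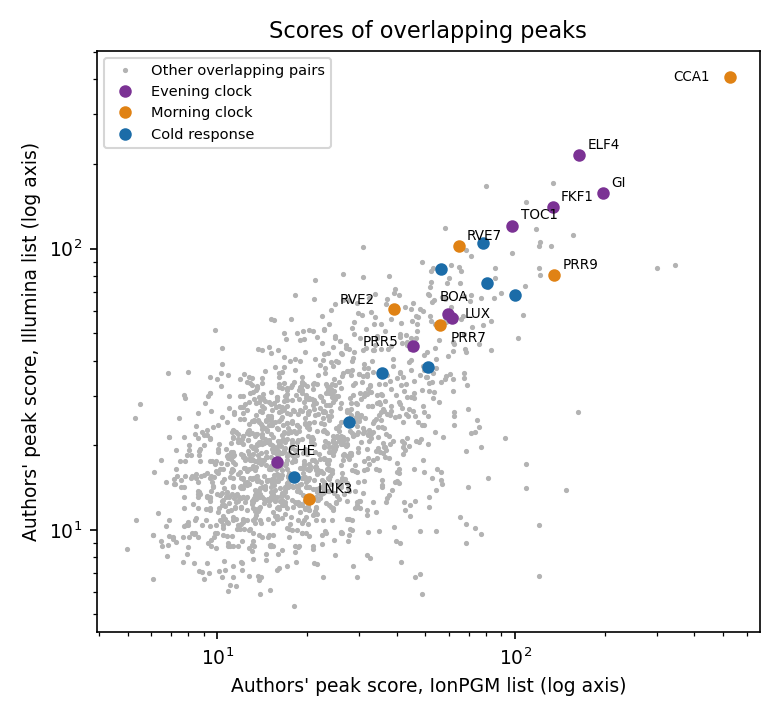
Authors' peak score in the IonPGM list (x, log axis) against that in the Illumina list (y, log axis) for the 1532 overlapping pairs (grey points), with the highest-ranked shared pair of each bound evening clock, morning clock and cold response gene in colour. CCA1 has the highest score on both axes, and GI, ELF4, FKF1 and TOC1 lie near the upper end.

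The highest unshared peaks differed in place between the lists. The 3 highest unshared IonPGM peaks were nearest to AT2G08986 (chromosome 2: 3625802 to 3626483), NAC097 (chromosome 5: 20680028 to 20680362) and AT5G29560 (chromosome 5: 11185519 to 11186043), and the first and the third lay in gene-poor regions. The 3 highest unshared Illumina peaks were on the chloroplast and mitochondrial genomes. Among the next Illumina peaks, which were named after their values were seen, were peaks at IDD4, COR47 (a dehydrin of the cold response) and TIC (a clock regulator).

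The second comparison places the peaks relative to genes. Binding concentrated at the ends of protein-coding genes in both lists, and far less inside them in the Illumina than in the IonPGM list. Centres at a gene end (1000 bp outside to 200 bp inside) made up 52.4% of nuclear IonPGM peaks and 65.4% of nuclear Illumina peaks, against 29.0% on average in random placements of either list (one-sided p = 0.001 each by random permutation of peak positions, the smallest possible). Of the 1499 nuclear shared segments, 47.2% had their centre outside a gene within 1000 bp of its end, against 20.4% in random placements, and 20.2% had it inside a gene, against 45.6%. Unshared peaks differed: 42.8% of 1361 unshared IonPGM peaks had their centre inside a gene, against 17.6% of 1394 unshared Illumina peaks (two-sided Fisher's exact p = 1.2e-47). Random placement of these peaks gave 45.45% and 45.4%, so neither share was above it. The Fisher test compares 2 libraries.

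**Figure D3:**
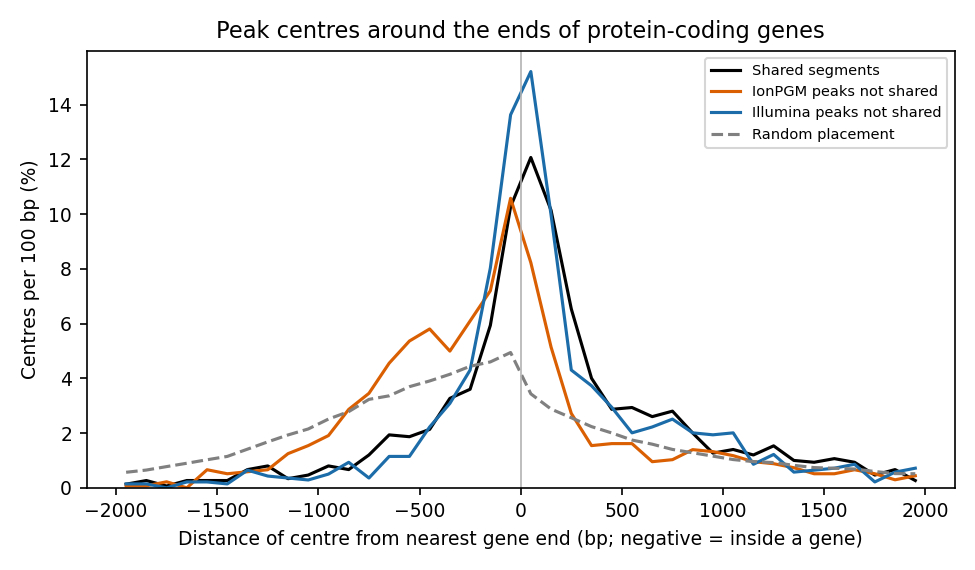
Percentage of centres per 100 bp (y axis) by distance from the nearest end of a protein-coding gene (x axis, in bp, negative inside a gene), for shared segments (black), unshared IonPGM peaks (orange), unshared Illumina peaks (blue) and random placements (dashed). Shared segments and the unshared peaks of both lists gather close to gene ends. Of unshared IonPGM centres 25.6% lie outside a gene within 1000 bp of its end, against 20.4% in random placements of these peaks. Inside genes lie 42.8% of them, against 45.45% in those placements.

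The third comparison asks which genes carry CCA1 at an end. In total 1602 genes (5.84% of 27444) had a shared segment in their window, and 1119 of the 1499 shared segments (74.7%) lay in at least 1 window. Because windows of neighbouring genes overlap and strand was not used, 1 segment can count for several genes, and a bound gene can be the neighbour of the intended one. Using the peaks of 1 list alone gave 2791 (IonPGM) or 3181 (Illumina) genes, and the peaks with a score percentile above 50 in each list gave 816.

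Most evening clock genes were bound. Of 12 evening genes 8 (66.7%, interval 34.9 to 90.1%) had a shared segment at an end, against 5.81% of other genes (one-sided Fisher's exact test, adjusted p = 5.8e-07). TOC1 (AT5G61380), a repressor of CCA1, had a segment at chromosome 5: 24674745 to 24675088, with IonPGM and Illumina score percentiles of 98.2 and 99.7. The percentiles were 99.6 and 99.9 at GI, 99.4 and 99.97 at ELF4, 99.0 and 99.8 at FKF1, 95.5 and 96.6 at LUX and 95.2 and 96.99 at BOA, where LUX and BOA encode related DNA-binding partners of ELF4. PRR5, a pseudo-response regulator, had a segment at 91.6 and 94.1, and CHE, a TCP-class repressor of CCA1, had one at 51.5 and 58.1. ELF3, PRR3 and LKP2 had no peak of either list within 1000 bp, and ZTL had 1 unshared Illumina peak at an end of the gene, at percentile 12.5.

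Of the 14 morning clock genes 6 (42.9%, interval 17.7 to 71.1%) were bound (Fisher's exact test, adjusted p = 0.00015). These were CCA1 and the pseudo-response regulators PRR9 and PRR7, with mean percentiles of 100, 98.9 and 95.2, the CCA1-related MYB genes RVE7 (97.8) and RVE2 (93.1), and LNK3 (49.2), of a family of transcriptional coactivators. LNK3 stood at percentile 66.8 in the IonPGM and 31.7 in the Illumina list. The count includes CCA1 itself, where a contribution of extra transgene copies cannot be told apart from binding. RVE1, RVE4, RVE6 and RVE8 had no peak of either list within 1000 bp, and LNK1, LNK2 and LNK4 had unshared peaks only. LHY, the closest relative of CCA1 and itself mutated in these cca1 lhy plants, was not bound at an end. Inside LHY the IonPGM list had a peak of 1519 bp at chromosome 1: 34055 to 35573 with percentile 98.8, and the 2 Illumina peaks overlapping it had percentiles of 15.6 and 2.13.

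Of the cold response genes 8 of 15 were bound (53.3%, interval 26.6 to 78.7%, Fisher's exact test, adjusted p = 3.2e-06). The 4 with the highest mean percentile were CBF1 (98.5) and CBF3 (98.1), tandem transcription factor genes of cold acclimation, and COR27 (98.1) and COR28 (96.8), cold-regulated genes that act in the clock. The CBF1 segment lay at chromosome 4: 13023416 to 13023835 and the COR27 segment at chromosome 5: 17199685 to 17199996. Starch metabolism genes followed with 7 of 14 (interval 23.0 to 77.0%, Fisher's exact test, adjusted p = 2e-05), led by PHS1 (92.1), a plastid starch phosphorylase, DPE1 (84.1), a plastid disproportionating enzyme, GWD1 (77.6), a glucan water dikinase, and PHS2 (55.3), a cytosolic phosphorylase. PHS2 stood at percentile 31.9 in the IonPGM and 78.7 in the Illumina list. The shared peaks of both lists at PHS2 lay wholly within the gene, so that call rests on the 200 bp inside a gene end.

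Light signalling genes were bound in 7 of 18 cases (38.9%, Fisher's exact test, adjusted p = 0.00011). The leading members were the red-light photoreceptor gene PHYB (95.1), the growth-promoting factor gene PIF4 (88.2), the B-box gene BBX25 (70.5) and the blue-light photoreceptor gene CRY2 (62.3). CRY2 stood at percentile 45.9 in the IonPGM and 78.8 in the Illumina list. At PIF4 the shared peaks of both lists lay wholly within the gene. That call rests on the 200 bp inside a gene end and cannot be told apart from signal along the gene. The highest Illumina peak at PIF4, at percentile 94.3, lay outside the gene and was unshared. Light-harvesting and chlorophyll synthesis genes were bound in 8 of 26 cases (30.8%, Fisher's exact test, adjusted p = 0.00015), led by PORB (99.2), LHCB2.1 (92.7), HEMA1 (85.7), of tetrapyrrole synthesis, and GUN4 (78.3). The shared IonPGM peaks of LHCB2.1 (1166 bp), GUN4 (736 bp), LHCB2.2 (906 bp) and LHCB1.5 (845 bp) lay wholly within the gene. Their calls rest on the 200 bp inside a gene end and cannot be told apart from signal along the gene. At PORB, HEMA1 and LHCB4.1 peaks of both lists lay across an end, and at LHCB3 only the IonPGM peak did. In this list 18 of 26 genes had an IonPGM peak centred inside the gene and 9 an Illumina peak, against 825 and 526 of all genes. Housekeeping genes, a control list, had one in 5 of 16 cases with IonPGM and in 3 of 16 with Illumina, and phenylpropanoid genes in 6 of 13 and 1 of 13.

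Smaller shares were found elsewhere. Photoperiodic flowering genes were bound in 3 of 12 cases (Fisher's exact test, adjusted p = 0.04): COL9 (97.3), a CONSTANS-like gene, CDF1 (67.5) and CDF5 (57.0), which encode Dof-type repressors of CONSTANS. The mean for CDF5 joins unlike percentiles, 90.55 in the IonPGM and 23.4 in the Illumina list. CO and FT, named after their values were seen, had no peak of either list within 1000 bp. Abscisic acid genes were bound in 3 of 12 cases (Fisher's exact test, adjusted p = 0.04): ABI2 (86.4) and PP2CA (74.5), phosphatases, and ABI5 (77.9), a bZIP factor. By the same exact test, the flowering and abscisic acid calls were lost with windows of 500 bp (adjusted p = 0.12 each) and with named genes as background (0.083 each, chosen after seeing the data), and the abscisic acid call also with the IonPGM list (0.13). Auxin genes did not pass (3 of 15, Fisher's exact test, adjusted p = 0.065), with ARF6, IAA3 and IAA1 bound. Phenylpropanoid genes (1 of 13, PAP1, adjusted p = 0.54) and housekeeping genes (2 of 16, ACT7 and GAPC1, adjusted p = 0.26) did not pass Fisher's exact test either. At PAP1 the shared peaks of both lists lay wholly within the gene.

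Set directly against the 16 housekeeping genes, a comparison chosen after seeing the data, only the evening clock list stood higher by a one-sided Fisher's exact test (adjusted p = 0.048), and cold response (0.096), starch (0.11), morning clock and light signalling (0.17 each), light harvesting (0.27), flowering and abscisic acid genes (0.45 each) did not pass. Housekeeping genes themselves passed against all other genes with the peaks of either sequencer alone, 5 of 16 in the IonPGM list (adjusted p = 0.029) and 7 of 16 in the Illumina list (adjusted p = 0.0017), both by Fisher's exact test.

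**Figure D4:**
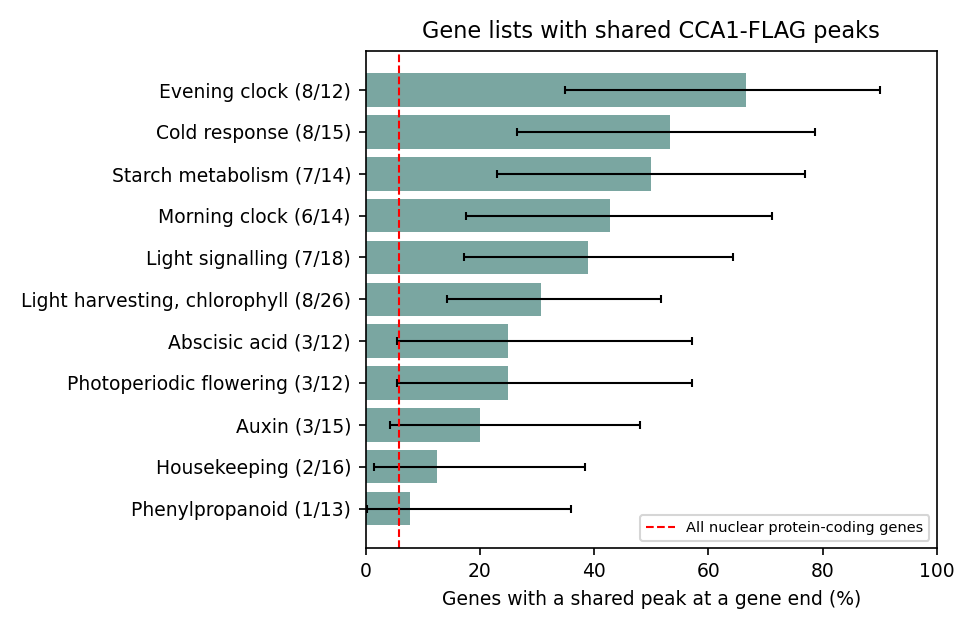
Percentage of the members of each fixed gene list with a shared segment at a gene end (x axis), with exact 95% intervals and the number bound of the members tested beside each name. The dashed line marks the 5.84% of all nuclear protein-coding genes: the evening clock list is highest with 8 of 12, and the phenylpropanoid list lowest with 1 of 13.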

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

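The tests on gene-poor regions, on gene bodies outside them, on transcribed genes, LHCB copies and the transgene, and that of the light-harvesting list against other genes were chosen after the result was seen. The test of gene bodies among all high IonPGM peaks was fixed before its result was seen.

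The 2 libraries of the same protein differed in where their unshared peaks fell: 42.8% of unshared IonPGM peaks were centred inside a gene, against 17.6% of unshared Illumina peaks. Random placement gave 45.45% and 45.4%, so the IonPGM share is no excess over chance and the Illumina share lies far below it. Within the light-harvesting and chlorophyll list, 9 genes had an IonPGM peak inside and no Illumina peak inside, and 0 the reverse (exact sign test, adjusted p = 0.035). Among all genes the same split was 536 to 237, and the list did not pass against the other genes (two-sided Fisher's exact p = 0.064, adjusted 0.42), so it is not shown to stand apart from the general difference between the lists. These 9, named after their values were seen, are LHCA2, LHCA3, LHCB1.1, LHCB1.2, LHCB2.1, LHCB5, LHCB6, CHLH and CAO. The IonPGM peak inside LHCB2.1 is itself shared: the Illumina peak that overlaps it lies across an end, so its centre does not count as inside. The housekeeping genes, which have no stated link to CCA1, also carried IonPGM peaks inside more often than other genes (31.25% against 2.99%, one-sided Fisher's exact p = 8e-05), and so did phenylpropanoid (6 of 13), light signalling (5 of 18), flowering (3 of 12), starch (3 of 14) and cold response genes (3 of 15), each past the threshold after adjustment. The excess was not particular to IonPGM: Illumina peaks also lay inside housekeeping (3 of 16, adjusted p = 0.012), light-harvesting (9 of 26, 8.4e-09), light signalling (3 of 18, 0.013) and auxin genes (3 of 15, 0.012) more often than inside other genes by one-sided Fisher's exact test. Signal over transcribed genes, for which no expression data were used, may account for part of these peaks. Reads shared between the near-identical LHCB1 and LHCB2 copies are argued against as the whole cause, because 48.6% of the other light-harvesting, chlorophyll and housekeeping genes had an IonPGM peak inside, against 2.95% of other genes. Library kit, sequencer and a possible difference between plants stay open. No biological explanation was tested for any of the 3 patterns, because the design has no groups of plants to compare.

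The second pattern is the lower sharing in the highest IonPGM score decile (72.5%, interval 67.0 to 77.6%) than in the ninth (78.2%, 73.0 to 82.8%). That difference was not tested, and the intervals overlap. Of the unshared nuclear peaks in the top score decile, 50% lay in gene-poor regions, against 1.94% of the shared ones (two-sided Fisher's exact p = 1.1e-21), and sharing among top-decile nuclear peaks went from 72.5% to 83.8% without those regions. Signal from repeats in gene-poor chromosome parts is thus a candidate explanation for that part of them. The share centred inside a gene, 32.1% of unshared against 24.8% of shared top-decile peaks, did not pass (two-sided Fisher's exact p = 0.23). Outside gene-poor regions, however, 19 of 39 unshared peaks (48.7%) were centred inside a gene, against 50 of 202 shared ones (24.75%, two-sided Fisher's exact p = 0.0036), so signal over gene bodies is a candidate explanation for part of those. Random placement of all unshared IonPGM peaks over whole chromosomes, gene-poor regions included, put 45.45% inside genes. The random rate outside those regions was not computed, so scattered background stays open. In the Illumina list 0 of 23 unshared top-decile peaks lay in gene-poor regions.

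The third pattern is the first rank of CCA1 in both lists, in cca1 lhy mutants whose transgene carries the CCA1 promoter and gene. Extra copies of the whole transgene would raise reads along promoter and gene alike, and peaks covered at most 3.10% of the length of CCA1 (2.59% in the IonPGM list). An even rise in reads need not be called as a peak, and the threshold and control are unknown, so this low cover excludes nothing. A contribution of extra copies, by their reads or by binding to their promoter, cannot be told apart from strong binding at CCA1 itself.

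Peaks on organelle genomes, where a nuclear transcription factor is not known to act, were counted in the comparison of the lists but were outside those with genes. The chloroplast carried 50 IonPGM and 49 Illumina peaks, of which 27 and 29 were shared. Over all peaks 52.2% and 51.6% were shared, so sharing on the chloroplast was no lower. Overlap by chance within the chloroplast, where the peaks covered 25.6 kb and 25.5 kb, was not measured. The sharing there thus cannot be weighed against that over all peaks. With no control library known, being shared does not by itself show binding of CCA1. The mitochondrial genome carried 17 Illumina peaks and 3 IonPGM peaks, with 0 shared.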

How the results depend on the processing

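Sharing between the lists, the higher ranks of shared peaks, the correlation of scores and the excess at gene ends kept their direction and stayed past the threshold under every alternative run; the percentage of IonPGM peaks shared ranged from 42.5% (top 200 of each list) to 53.3% (gene-poor regions left out, an alternative chosen after seeing the data). The number of bound genes depended on the peak set: 1602 became 2791 with the IonPGM list, 3181 with the Illumina list and 4288 with either list. It became 816 with the peaks above score percentile 50 of each list, and all these changes follow from the construction of the peak sets. The gene window mattered too, with 1212 genes at 500 bp and 2243 at 2000 bp. With the nearest gene end 1412 genes were called, of which 1045 were among the 1602. Evening clock genes passed under every alternative run, with adjusted p from 4.8e-07 to 0.048. Against housekeeping genes by Fisher's exact test the calls of morning clock (6 bound, adjusted p = 0.17), light signalling (7, 0.17), cold response (8, 0.096), light harvesting (8, 0.27), starch (7, 0.11), flowering (3, 0.45) and abscisic acid genes (3, 0.45) were lost; that control holds only 16 genes. By the same exact test, flowering and abscisic acid genes also lost their call with windows of 500 bp (2 bound each, adjusted p = 0.12) and with named genes as background (3 each, 0.083), and abscisic acid genes with the IonPGM list (3, 0.13). Auxin genes passed with windows of 500 bp (3, 0.041) or 2000 bp (4, 0.036), with the nearest gene end (5, 0.0011), with whole genes (4, 0.019) and with rotated segments (3, 0.02). Phenylpropanoid genes passed with either list (5, 0.044) and fell below the background with 2000 bp windows (1 bound, 0.67), named genes (1, 0.65) and housekeeping genes (1, 0.85). Housekeeping genes passed with the IonPGM list (5, 0.029), the Illumina list (7, 0.0017), either list (9, 0.00035), the nearest gene end (5, 0.0013) and whole genes (5, 0.0045). All these are adjusted p-values of one-sided Fisher's exact tests, except the rotation, and their causes were not tested. Named genes, whole genes, rotation and the housekeeping comparison were added after seeing the data. No peak was wider than 5 kb, so that filter removed none. The planned motif alternatives were not run, and windows at the transcription start became windows at either gene end. No paired analysis was possible because each sequencer has 1 library, which also leaves no replicate to leave out. Depth is unknown, so a gene without a peak is not shown to be unbound.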

Other observations

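The tests of tRNA genes and symbol families were fixed before their results were seen; the local moves of peaks and the genes named in the next paragraph were chosen after.

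The 11th-ranked shared pair, at chromosome 5: 8359704 to 8360121 (IonPGM), had no protein-coding gene in the 1000 bp window. Its nearest gene was PRR5, of the evening clock list. Beyond the fixed lists, high-ranked shared pairs lay at several other regulators. TPR1, a TOPLESS-related corepressor gene, shared the 12th-ranked pair with PTAC17. The cytokinin response factor genes CRF3 and CRF4 had pairs with mean percentiles of 98.0 and 97.7, NAC019 had one at 98.5, and HAI2, a phosphatase gene of abscisic acid signalling, one at 97.6.

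Among 201 families of at least 8 genes with a common symbol stem, 1 held more bound genes than other named genes at an adjusted one-sided Fisher's exact p under the threshold. It was ERD, genes named for early response to dehydration, with 6 of 13 bound (46.2% against 7.70%, Fisher's exact test, adjusted p = 0.046): ERD3, ERD4, ERD7, ERD10, ERD14 and ERD15. The symbol stem BBX followed with 6 of 19 (Fisher's exact test, adjusted p = 0.24) and the JAZ repressors of jasmonate signalling with 4 of 10 (adjusted p = 0.34), which did not pass. Genes of a stem are named by history, so ERD is not a family by sequence, and the BBX stem misses bound B-box genes listed under other symbols, such as BBX22 and BBX25.

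Shared segments lay at some classes of RNA genes more often than in random placements, and at other classes not. Of 625 nuclear tRNA genes, 35 (5.60%) had a shared segment within 200 bp, against 0.944% on average in random placements (one-sided p = 0.001 by random permutation of positions, the smallest possible) and 0.819% after moving each segment 5000 to 20000 bp. Unshared Illumina peaks lay at 58 tRNA genes (9.28%) and unshared IonPGM peaks at 17 (2.72%); the difference between lists was not tested. Of 82 snRNA genes 7 had a shared segment (the same permutation, adjusted p = 0.0051), and of 287 snoRNA genes 0 did. Of 326 miRNA genes 3 had one (0.920%, against 1.02% in random placements), which did not pass. Of 3480 lncRNA genes 130 had one (3.74% against 1.49%, the same permutation, adjusted p = 0.003). Unshared peaks lay at 2.53% (IonPGM) and 2.33% (Illumina) of them, against 1.385% and 1.386% (the same permutation, adjusted p = 0.003 each). Of shared segment centres 62.6% lay at protein-coding gene ends, against 29.1% in random placements. Neither the placements nor the local moves kept that gathering, so the lncRNA excess cannot be told apart from it. Where RNA genes lie relative to those ends was not examined. Signal at strongly transcribed RNA genes that does not depend on CCA1 may contribute, which an untagged control would test. Pseudogenes had a shared segment in 5 of 3917 cases, or 0.128%, against 3.71% in random placements and 1.05% after the local moves, and depletion was not tested.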
